A study of Caenorhabditis elegans with 10 samples.

How the data were processed

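The series holds RNA immunoprecipitation followed by sequencing from synchronized young adult worms that carry 3xFLAG::DLC-1. Per the labels, cleared whole-worm extract was incubated with an antibody against FLAG, and RNA was purified from the eluates and from the inputs with the same reagents. Per the labels' protocols, input libraries were started from total RNA by oligo-dT priming, while the immunoprecipitated RNA was made into libraries without an enrichment step. Library preparation and group are therefore the same split of the samples. That the immunoprecipitates were not primed with oligo-dT is inferred from the missing enrichment step. The 10 samples were placed in the groups FLAG immunoprecipitate (5) and input (5) by their titles.

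The submitters' processing notes name Trim Galore, Bowtie2 2.3.0, STAR 2.5.2b-0 and DESeq2 1.12.3 and the genome builds WBcel235 and ce11, without their roles or order. The counting method, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The one processed file is a table of the authors' own comparison with 2732 genes. Per the file headers it gives for each gene a mean signal over the libraries (baseMean, a mean normalized count), a log2 fold change of immunoprecipitate over input and its standard error. It also gives a test score (stat) and a p-value with its adjusted p-value, per the file headers. The authors' table was tested for its selection: its lowest log2 fold change is 1.00, above a threshold of 1, and every adjusted p is under a threshold of 0.01. The deposited score is the log2 fold change divided by its standard error. The deposited p-value is the upper tail of the normal distribution of that score, to a relative tolerance of 1e-06, for all 2725 genes with a p above 0, and 7 are listed at 0. The authors' test is therefore one-sided.

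The adjusted p-values follow Benjamini and Hochberg, and the number of genes behind them was recovered from the gene with the smallest p above 0. Its rank was assumed to come directly after the 7 genes listed at 0, and whole ranks of the other genes served as a check. With 20328 tested genes, 96.2% of the implied ranks of listed genes are whole to a tolerance of 0.0001. The same ranks imply 3494 genes past the adjusted p threshold, so 762 of them are not in the table, which holds only folds above 2. The one-sided test puts the folds of these 762 above 1, and below 2 if the fold threshold alone left them out. Their own fold changes are not known. The table has no values per library. No library's depth, total or spread could be computed, no model was refitted, and the fold changes and p-values of single genes are described as the authors gave them. For the same reason the number of members adjusted over the list alone could not be given.

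Gene names were matched to a table of the genes of the WBcel235 assembly with 46926 genes. Of the 2732 names, 2493 matched by symbol, 167 by locus tag and 4 by the other name of a mitochondrial gene, which is 97.5% in all, and 68 stayed unmatched and out of tests that need the reference. Locus tags were replaced by the reference's symbols (*vps-13D* for C25H3.11, *scpr-1* for Y6B3B.4, *wshc-4* for Y53F4B.21 and *edc-4* for Y44E3A.6). RNA class, chromosome and coordinates come from that reference. It gives the span of each gene with introns and no transcript length, so gene span stands in for the transcript length that had been planned.

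The tests and alternatives were chosen before the data were examined, with separate plans for counts, for normalized values and for a table of the authors' comparison, and the last was used. There were 20 gene lists, also fixed before the data were examined: targets of GLD-1, of FBF, and of OMA-1 and LIN-41; germ granule and germline RNA-binding proteins; eggshell and oocyte-to-embryo transition; meiotic axis, synapsis and crossover; cell cycle and DNA replication; sperm; P body and deadenylation; dynein and dynactin; cytosolic ribosomal proteins; proteasome; mitochondrially encoded genes; histones; vitellogenins; muscle; intestine; neurons; collagens and cuticle; and structural non-coding RNAs. The members of the target lists and tissue lists were named from general knowledge of the worm. Some genes are in several lists. In the P body list 2 names were not found in the reference. Each list's share in the table was compared with that of all other reference genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 20 lists at a threshold of 0.05. Where a list had no listed member, 0.5 was added to each cell for the odds ratio. Because the set of tested genes is not in the table, the background holds genes that are not expressed in adults, and any list of expressed genes tends to exceed it.

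Protein-coding genes as background were an alternative chosen before the data were examined. An exact test within 20 bins of gene span, with the Mantel-Haenszel odds ratio, was added after the data were seen, as were counts of genes past a test against 2-fold and of genes with a mean of at least 100, and a background without piRNA genes. Benjamini-Hochberg adjustment in these tests runs over the lists tested. For lists with 3 or more listed protein-coding genes, the median fold was placed among 10000 random draws of the same size, matched on mean expression. Draws came from the listed protein-coding genes alone, without the non-coding genes of the table. The percentile was 100 for histones, 99.25 for muscle, 90.3 for GLD-1 targets, 83.6 for P body genes and 81.3 for neurons. It was 44.3 for FBF targets, 42.7 for meiosis, 42.4 for mitochondrially encoded genes, 37.4 for the cell cycle, 37.1 for dynein, 6.18 for germline RNA-binding proteins and 3.52 for vitellogenins. X-linked and autosomal genes were compared by Fisher's exact test. Spearman's rho was taken across genes with 100000 permutations.

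Named genes follow a rule set before the data were examined. It takes *dlc-1*, the 10 highest fold changes among protein-coding genes with a mean at or above the table's median (222 normalized counts), the 5 highest means, and up to 3 members of each list with the smallest adjusted p. Since histones took all 10 of the first places, the 10 highest folds outside the histones were added after the values were seen, as were examples of the non-coding classes and of nucleoporins.

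The test within span bins was tried on simulated data. Over the 19983 protein-coding genes, 200 lists of 45 long genes were drawn with no true excess, and Fisher's exact test without span bins called 94% of them at a p of 0.05, against 5% for the test within bins. With a true odds ratio of 4, the 2 tests called 100% and 99.5%. Listing was simulated at a constant rate within each of the same 20 bins, so the 5% cannot show that span differences inside a bin are harmless. All simulated members came from the longest bins, which hold 31.1% of the germline RNA-binding protein list, so the 94% does not describe that list. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.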

Results

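RNA was sequenced from 5 FLAG immunoprecipitates and 5 input extracts of young adult *Caenorhabditis elegans* carrying 3xFLAG::DLC-1. DLC-1 is a light chain of the LC8 family, small proteins found in the dynein motor and in many other complexes. Extracts were made from whole worms, so germline and somatic RNA were both present. According to the series' design text, the tagged protein was pulled down to recover the ribonucleoprotein complexes it belongs to, and the comparison asks which RNAs came down with it. The labels number both groups from 1 to 5 and do not say whether the numbers stand for separate cultures, so the authors' p-values may measure technical spread alone. The file analysed here is the authors' table of enriched genes, which holds no values per sample, so the depth of each library is unknown. All 10 samples carry the tag, and immunoprecipitates from untagged worms were not analysed here.

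Histone genes, germline regulators, yolk protein genes and many non-coding RNAs were among the genes enriched in the immunoprecipitates. The authors' deposited table lists 2732 genes, all higher in the immunoprecipitates than in the inputs, with log2 fold changes from 1.00 to 11.40. Their median in the authors' deposited table was 2.13, or 4.36-fold, with a median standard error (SE) of 0.31. Of the 2732 genes, 1465 were at or above 4-fold, 685 at or above 16-fold and 378 at or above 64-fold. All have an adjusted p under 0.01 in the authors' deposited table, from a one-sided Wald-type test with Benjamini-Hochberg adjustment. Protein-coding genes made up 2120 of the genes, which is 10.6% of the 19983 in the reference. The gene for the bait, *dlc-1*, is not listed. Against a change of 2-fold in place of no change, 1350 genes passed the one-sided test at a Benjamini-Hochberg adjusted p of 0.01. Genes left out of the table may have been unchanged, depleted, enriched less than 2-fold or not expressed, and these cannot be separated here.

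Core histone mRNAs had the highest median fold change of the protein-coding lists tested. Of 72 genes named as histones, 63 were listed, with a median log2 fold change of 7.93 in the authors' deposited table (odds ratio 119, two-sided Fisher's exact test against all reference genes, Benjamini-Hochberg adjusted p = 1.65e-67). By the rule fixed for named genes, all 10 of the highest folds belonged to histones. In the authors' deposited table *his-44* stood at 8.995 ± 0.23 (log2 fold change ± SE), *his-15* at 8.995 ± 0.23 and *his-11* at 8.92 ± 0.23, all on chromosome II within 13818371 to 13827098 of WBcel235. The others were *his-46*, *his-56*, *his-29*, *his-34*, *his-16*, *his-1* and *his-4*, between 8.36 and 8.81 in the authors' deposited table. The 9 histone genes not listed were *his-24*, *his-35*, *his-37*, *his-41*, *his-69*, *his-70*, *his-71*, *his-72* and *his-74*. Histone copies are near-identical in sequence, and 16 of the 63 share their values with another copy to within 0.1% of the mean and 0.01 in log2 fold, so the value of any single copy is uncertain. The inputs were primed with oligo-dT and the immunoprecipitates were processed without enrichment. RNAs that lack poly(A) tails, as most core histone mRNAs are known to, may therefore have been captured differently in the 2 groups.

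Small structural RNAs were also listed with high folds. Of 129 small nuclear RNA genes 21 were listed, or 16.3%, and of 346 small nucleolar RNA genes 64, or 18.5%. In the authors' deposited table the 21 small nuclear RNAs had a median log2 fold change of 7.51, the 64 small nucleolar RNAs 5.35, the 317 unclassified non-coding RNAs 6.57 and the 21 long non-coding RNAs 5.61, against 1.81 for protein-coding genes. The highest value of the authors' deposited table was that of the small nucleolar RNA ZK185.9, at 11.40 ± 0.43 (log2 fold change ± SE). The ribosomal RNA pseudogene *rrn-3.56* followed, at 10.59 ± 0.44 in the authors' deposited table. C30E1.9, a non-coding RNA of chromosome X (16929914 to 16944683, WBcel235), stood at 3.20 ± 0.14 in the authors' deposited table. Of the 634 transfer RNA genes 2 were listed, and none of the 260 microRNA, 15363 piRNA or 22 ribosomal RNA genes. Whether the unlisted genes of these classes were among the 20328 tested is not known, so their absence does not show a lack of enrichment. Of the 7762 unclassified non-coding RNA genes 4.08% were listed. These and the transfer RNAs make up most of the list of structural non-coding RNAs, which as a whole was under-represented, with 434 of 9190 genes (odds ratio 0.789, two-sided Fisher's exact test against all reference genes, Benjamini-Hochberg adjusted p = 3.02e-05). The size of the deficit depends on the 15363 piRNA genes in the background, none of them listed: without them the odds ratio was 0.448, and among genes past the test against 2-fold it was 1.04 with them and 0.603 without. Counting as listed only genes with a mean of at least 100 normalized counts gave 0.0557. Most of these RNAs rested on few reads, with a median of 2.78 normalized counts in the authors' deposited table, and the difference in library preparation applies to them as well. The median mean was 2.51 for unclassified non-coding RNAs, 3.56 for long non-coding RNAs and 6.18 for small nucleolar RNAs, against 377 for protein-coding genes. A gene with a low mean can only enter the table with a high fold, so the contrast of class medians is partly set by the selection.

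**Figure D1:**
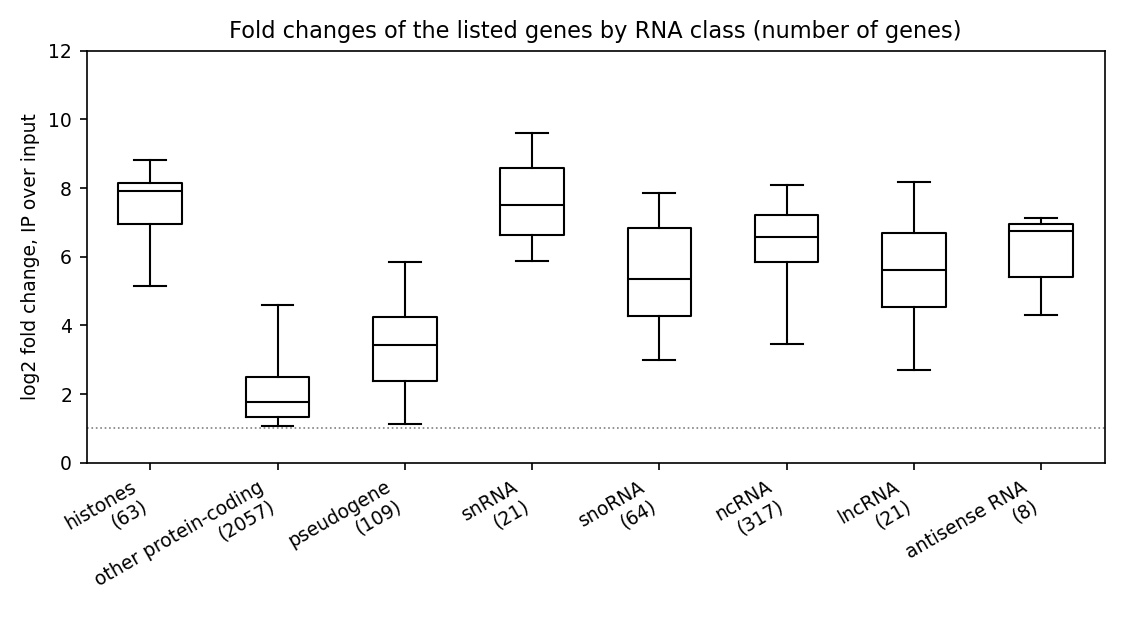
Log2 fold change of immunoprecipitate over input (vertical axis) for the listed genes of each RNA class, with the number of genes in parentheses. Lines mark medians, boxes the quartiles and whiskers the 5th and 95th percentiles, the dotted line is the 2-fold threshold of the authors' deposited table, and histones and non-coding classes sit above the other protein-coding genes, whose median is 1.78. Genes with low means, as in most non-coding classes, enter only with high folds, so the height of those classes is partly set by the selection.

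Genes for germ granule components and germline RNA-binding proteins were listed well above the background rate. Of 45 such genes 20 were listed, where 5.28 were expected from protein-coding genes of the same span (odds ratio 7.28, two-sided exact test within span bins, Benjamini-Hochberg adjusted p = 3.02e-08). Against all reference genes the odds ratio was 13.4 (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 9.03e-13). Their folds were modest, with a median log2 fold change of 1.57 in the authors' deposited table. Examples are *glh-4*, a Vasa-related helicase of P granules, at 1.42 ± 0.10, *gls-1* at 1.59 ± 0.12 and *nos-3*, a Nanos homologue, at 2.28 ± 0.18 (log2 fold change ± SE, the authors' deposited table). Chosen after their values were seen, *pgl-1*, *pgl-3*, *meg-1*, *meg-2*, *meg-3* and *meg-4* were listed too, all of them encoding germ granule proteins. Of the same gene list, *pgl-2*, *glh-1*, *glh-2* and *glh-3* were not.

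Messenger RNAs known as targets of the PUF proteins FBF-1 and FBF-2, which hold germline stem cells in their undifferentiated state, were over-represented, with 7 of 17 listed (odds ratio 11.7, two-sided Fisher's exact test against all reference genes, Benjamini-Hochberg adjusted p = 6.92e-05). The odds ratio of these targets was 5.91 against protein-coding genes and 10.7 within span bins. In the authors' deposited table the meiotic cohesin gene *rec-8* stood at 1.72 ± 0.15, the cytoplasmic poly(A) polymerase gene *gld-2* at 2.38 ± 0.22 and *fbf-2* itself at 2.73 ± 0.31 (log2 fold change ± SE). *fbf-1* and *fbf-2* are near-identical copies, and the split of reads between them is uncertain. The listed genes *gld-1*, *gld-2*, *fbf-1* and *fbf-2* are also in the list of germline RNA-binding proteins, so the excesses of these lists are not independent. Of 12 mRNAs known to be regulated by the translational repressor GLD-1, 3 were listed (odds ratio 5.54, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0420). They were the Notch receptor gene *glp-1* at 2.62 ± 0.23, *mes-3* at 2.56 ± 0.26 and the cyclin E gene *cye-1* at 1.77 ± 0.21 (log2 fold change ± SE, the authors' deposited table). Neither protein-coding genes as background (Benjamini-Hochberg adjusted p = 0.172) nor span bins (0.773) kept the call for GLD-1 targets in the exact tests. Targets of OMA-1 and LIN-41, regulators of oocyte maturation, did not pass, with 2 of 9 listed, *meg-1* and *cdc-25.3* (odds ratio 4.75, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.111).

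Cell cycle and DNA replication genes were over-represented, with 12 of 36 listed (odds ratio 8.34, two-sided Fisher's exact test against all reference genes, Benjamini-Hochberg adjusted p = 2.54e-06). Their odds ratio was 4.23 against protein-coding genes and 4.96 within span bins. The replication licensing gene *cdt-1* stood at 4.12 ± 0.31, the centriole gene *sas-4* at 2.05 ± 0.19 and the cyclin D gene *cyd-1* at 1.69 ± 0.17 (log2 fold change ± SE, the authors' deposited table). Genes of the meiotic chromosome axis, synapsis and crossover missed the threshold, with 4 of 24 listed, among them *chk-2* at 3.59 ± 0.47 and *msh-5* at 1.22 ± 0.13 in the authors' deposited table (log2 fold change ± SE). Their odds ratio was 3.33 (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0634), and it was 1.69 against protein-coding genes (adjusted p = 0.351) and 1.46 within span bins (adjusted p = 0.650) in the exact tests. Of 14 eggshell and oocyte-to-embryo genes, 2 were listed, the chitin synthase gene *chs-1* at 1.62 ± 0.090 and the eggshell gene *cbd-1* at 1.59 ± 0.090 (log2 fold change ± SE, the authors' deposited table). That list did not pass (odds ratio 2.77, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.220). Sperm genes were nearly absent, with 1 of 87 listed, *spe-15* at 1.23 ± 0.31 in the authors' deposited table (log2 fold change ± SE). Their deficit missed the threshold against all reference genes (odds ratio 0.193, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0854) and passed it against protein-coding genes (odds ratio 0.102) and within span bins (odds ratio 0.0712). Sperm genes are short, with a median span of 384 bp, and the shortest span bin had 7.90% listed with histones and 1.82% without. Histones therefore raised the 7.05 sperm genes expected within span bins, and the deficit without histones was not tested.

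**Figure D2:**
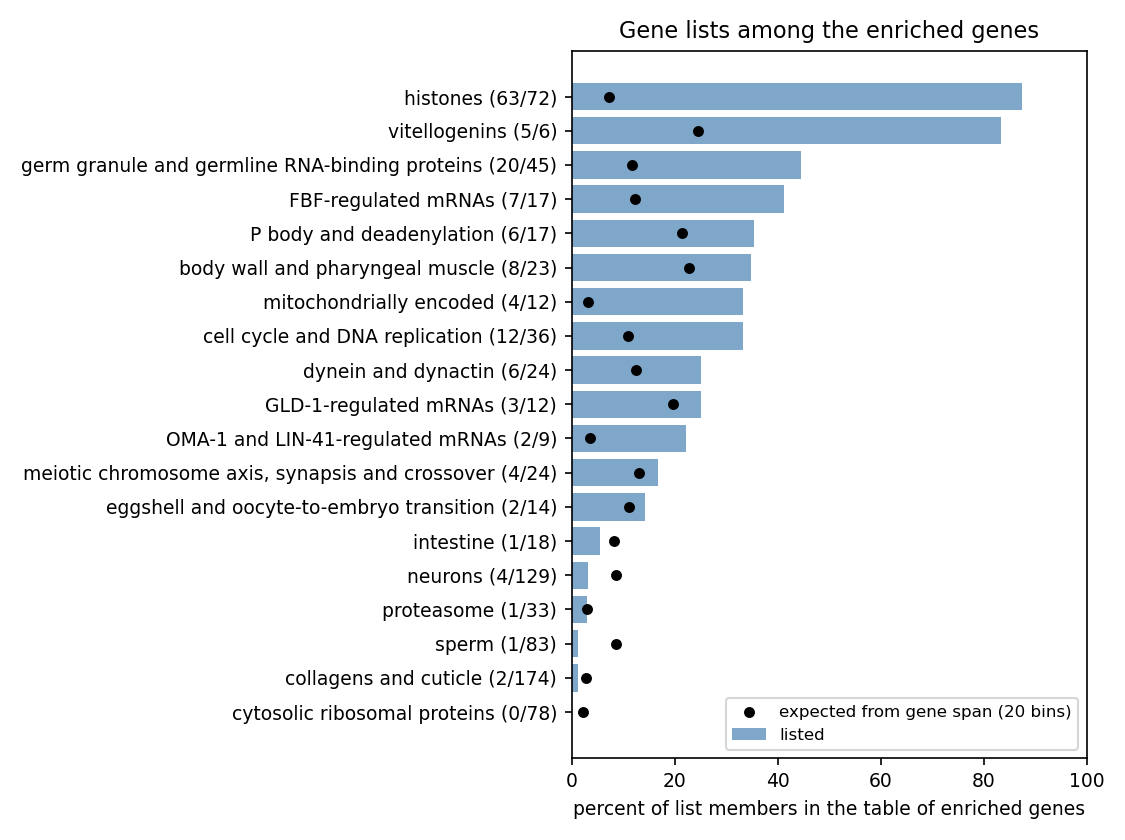
Percent of the protein-coding members of each fixed gene list that are in the authors' deposited table (bars, with listed and total members in parentheses). Black points give the percent expected from protein-coding genes in the same 20 bins of gene span, and histones and germline RNA-binding proteins lie far to the right of their points, while P body and muscle genes lie closer to theirs.

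The mRNAs of yolk proteins, made in the intestine for uptake by oocytes, made up 4 of the 5 highest means among the 2732 listed genes; genes not listed have no mean here. Of the 6 vitellogenin genes 5 were listed (odds ratio 83.2, two-sided Fisher's exact test against all reference genes, Benjamini-Hochberg adjusted p = 1.68e-05). Against protein-coding genes the odds ratio was 42.2. Within span bins it was 14.7, with 1.47 genes expected (exact test, Benjamini-Hochberg adjusted p = 0.0128). The means in the authors' deposited table were 101613 normalized counts for *vit-2*, 97891 for *vit-6*, 93063 for *vit-5* and 83871 for *vit-4*. Log2 fold changes in the authors' deposited table were 2.55 ± 0.15 for *vit-1*, 2.51 ± 0.16 for *vit-6*, 1.34 ± 0.19 for *vit-4*, 1.30 ± 0.17 for *vit-5* and 1.28 ± 0.21 for *vit-2* (± SE). Several vitellogenin genes are close copies, so their single values are uncertain. Other genes of the intestine were not over-represented, with 1 of 18 listed, the peptide transporter gene *pept-1* at 1.15 ± 0.20 in the authors' deposited table (odds ratio 0.977, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 1).

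Several muscle genes had high folds, among them those for giant sarcomere proteins. Of 23 body wall and pharyngeal muscle genes 8 were listed, with a median log2 fold change of 3.83 in the authors' deposited table (odds ratio 8.88, two-sided Fisher's exact test against all reference genes, Benjamini-Hochberg adjusted p = 6.92e-05). The twitchin gene *unc-22* stood at 5.03 ± 0.28, the titin-related *ttn-1* at 4.70 ± 0.24 and the obscurin-related *unc-89* at 3.72 ± 0.18 (log2 fold change ± SE, the authors' deposited table). These 3 genes span 38311, 81724 and 55184 bp. The other listed members, outside the rule for named genes, were *unc-54* at 4.35, *myo-2* at 3.93, *myo-3* at 3.43, *myo-1* at 2.75 and *unc-15* at 1.17 in the authors' deposited table (log2 fold change). High folds in this list were therefore not limited to the 3 giant genes. Within span bins the excess was not past the threshold, with 5.22 genes expected (odds ratio 2.49, exact test, Benjamini-Hochberg adjusted p = 0.252). Of 129 genes of neurons, neuropeptide genes included, 4 were listed (odds ratio 0.531, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.282), among them the synaptic genes *unc-13* at 1.94 ± 0.17 and *unc-31* at 2.91 ± 0.41 and the kinesin gene *unc-104* at 2.61 ± 0.33 (log2 fold change ± SE, the authors' deposited table). The list's deficit passed against protein-coding genes (odds ratio 0.268) and within span bins (odds ratio 0.232). None of its 78 *nlp* and 31 *flp* neuropeptide genes was listed, so all 4 listed genes were other neuronal genes. Those other genes were not tested alone, so the deficit does not describe neuronal genes at large. Any neuronal genes in the shortest span bin have an expectation raised by histones, and this deficit was not tested without histones. Collagen and cuticle genes were under-represented, with 2 of 177 listed, *col-99* and *bli-1* (odds ratio 0.189, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00877). Collagen genes are short, and within span bins 4.64 were expected and the deficit did not pass (odds ratio 0.338, exact test, Benjamini-Hochberg adjusted p = 0.453).

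Among genes of cellular machines, those for the dynein motor that DLC-1 belongs to were listed more often than all reference genes. Of 24 dynein and dynactin genes 6 were listed (odds ratio 5.55, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00410). The heavy chain gene *dhc-1* stood at 2.24 ± 0.18, the intermediate chain gene *dyci-1* at 1.82 ± 0.24 and the dynactin gene *dnc-1* at 1.55 ± 0.13 (log2 fold change ± SE, the authors' deposited table). The call did not hold against protein-coding genes (Benjamini-Hochberg adjusted p = 0.0521) or within span bins (0.123) in the exact tests. Of 17 P body and deadenylation genes 6 were listed, including the exonuclease gene *xrn-1* at 5.52 ± 0.71, *edc-4* at 2.14 ± 0.21 and *ntl-3* at 2.13 ± 0.21 (log2 fold change ± SE, the authors' deposited table). That excess (odds ratio 9.08, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.000598) did not hold within span bins either (odds ratio 2.53, Benjamini-Hochberg adjusted p = 0.278). None of the 78 cytosolic ribosomal protein genes was listed (odds ratio 0.106, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0385), while genes of their short span gave an expectation of 1.66 and no call (exact test within span bins, Benjamini-Hochberg adjusted p = 0.558). Of 33 proteasome genes 1 was listed, *rpn-2* at 1.15 ± 0.091 in the authors' deposited table (odds ratio 0.519, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 1). Of the 12 protein-coding genes of the mitochondrial genome 4 were listed, with *nduo-4* at 2.40 ± 0.26, *nduo-5* at 1.82 ± 0.19 and *ctc-1* at 1.74 ± 0.18 in the authors' deposited table (odds ratio 8.32, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00710).

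**Figure D3:**
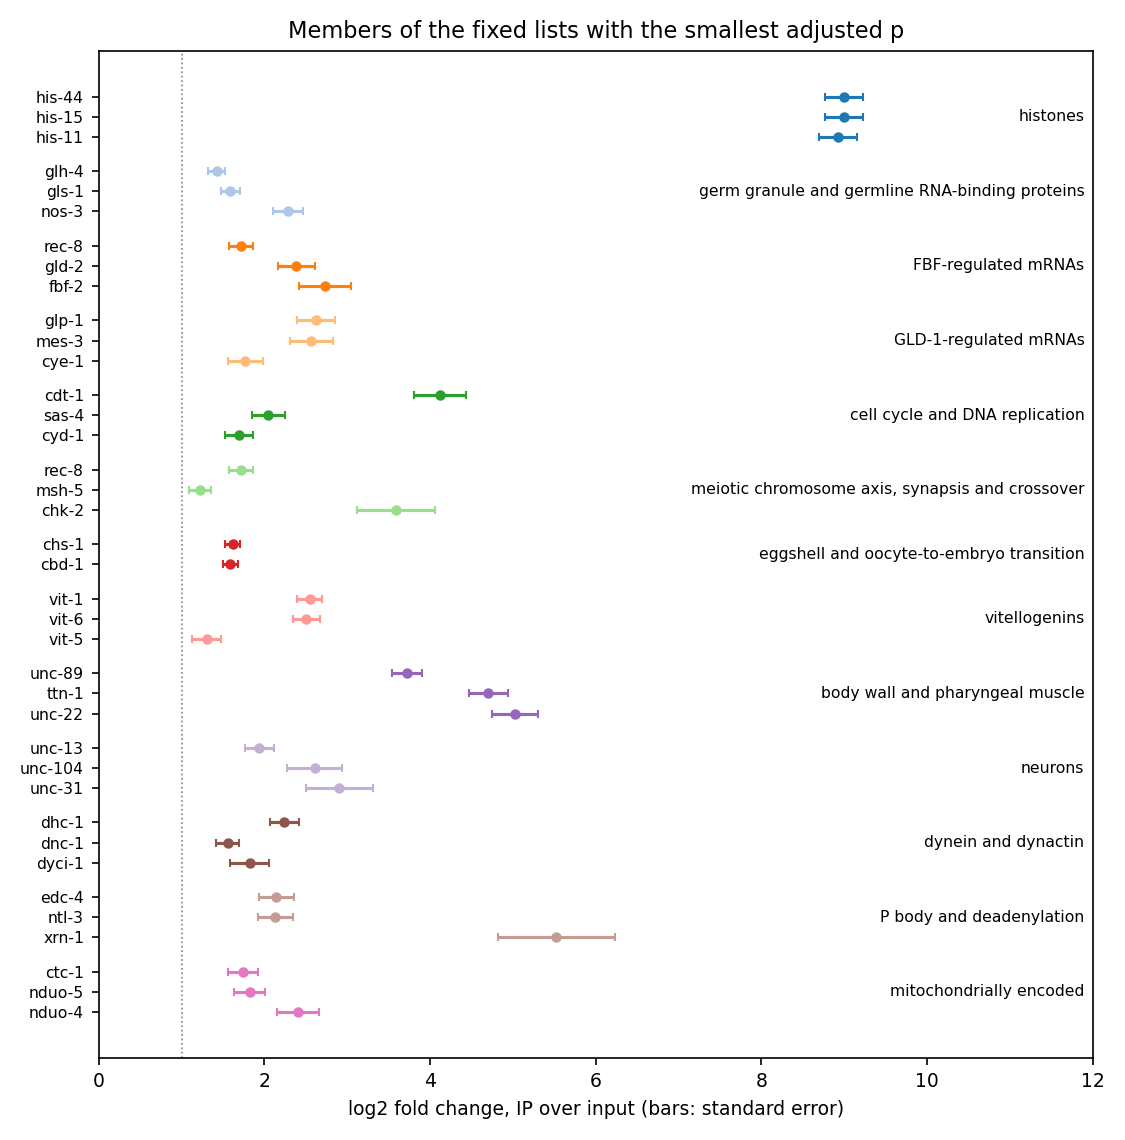
Log2 fold change of immunoprecipitate over input (horizontal axis) of up to 3 listed members of each of 13 gene lists, from the authors' deposited table. Points are the authors' estimates, bars their standard errors and the dotted line the 2-fold threshold, and the 3 histone genes lie near 9 while most germline genes lie between 1 and 3.

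Outside the histones, the highest folds among protein-coding genes with means at or above the table's median, a choice made after the values were seen, belonged mostly to long genes. *vps-13D* stood at 7.10 ± 0.46, the RasGAP gene *gap-3* at 6.95 ± 0.27, H05C05.1 at 6.77 ± 0.83, *anc-1* at 6.59 ± 0.30 and the AMP kinase subunit gene *aakg-1* at 6.39 ± 0.54 (log2 fold change ± SE, the authors' deposited table). *scpr-1*, *wshc-4*, ZC247.1, *plg-1* and *ssl-1* followed, between 5.79 and 6.05 in the authors' deposited table. *anc-1*, which encodes a giant protein anchoring nuclei, was also among the 5 genes with the highest means, at 67171 normalized counts in the authors' deposited table, and covers 41060 bp of chromosome I (4318033 to 4359092, WBcel235). *plg-1* is the exception in length, at 746 bp.

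Long genes were listed more often than short ones. The share of protein-coding genes listed rose from 1.00% in the bin of 874 to 1049 bp to 53.6% in the bin of the longest genes, 9809 bp and above. The shortest bin, up to 452 bp, reached 7.90% with histones and 1.82% without. Across the 1544 protein-coding listed genes other than histones with a mean of at least 100 normalized counts, fold rose with span (Spearman's rho = 0.32 across genes, permutation test, p = 1e-05, the smallest that 100000 permutations can give; Benjamini-Hochberg adjusted p = 2.2e-05 over 11 correlations). Over all 2120 listed protein-coding genes there was no such relation past the threshold (rho = -0.020, permutation test, p = 0.356). Among the 1544 genes, the median fold in the authors' deposited table was 2.66 in the 309 shortest (486 to 3619 bp) and 4.27 in the 309 longest (12529 to 81724 bp). Over all listed genes with a span the relation ran the other way (rho = -0.43), as did fold against mean expression (rho = -0.44), with short and weakly expressed non-coding RNAs at high folds. A gene with a low mean can only enter the table with a high fold, so both of these relations are partly set by the selection, and genes are not independent replicates.

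**Figure D4:**
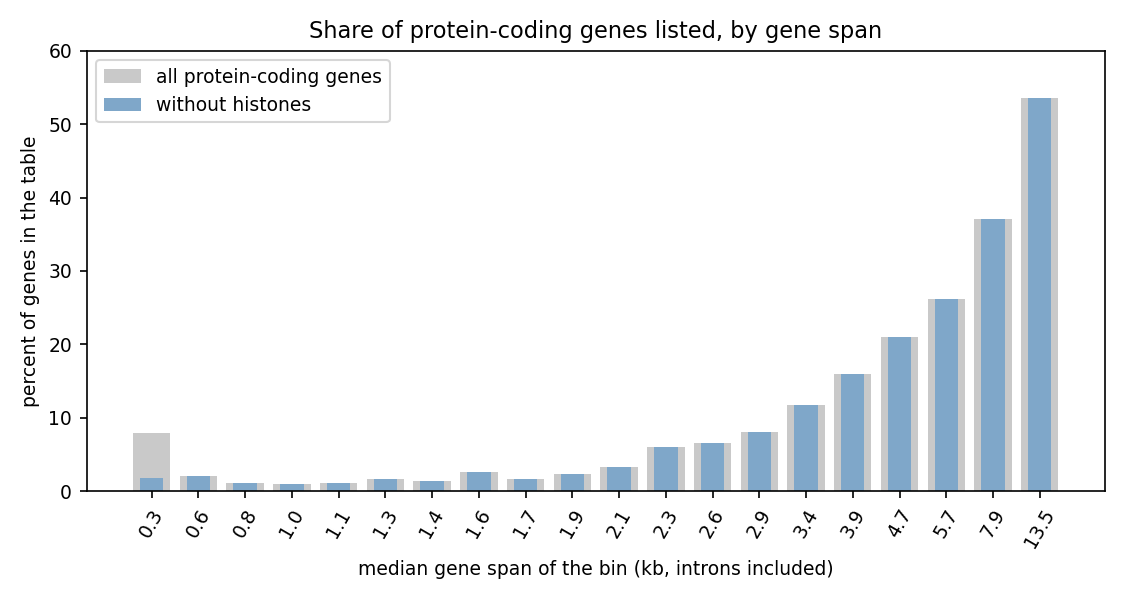
Percent of protein-coding genes in the authors' deposited table (vertical axis) in 20 bins of gene span, labelled by their median span in kb on the horizontal axis. Grey bars hold all protein-coding genes and blue bars leave out histones, and the share climbs from about the tenth bin to 53.6% in the last.

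Protein-coding genes of the X chromosome, many of them silent in the adult germline, were listed somewhat more often than autosomal ones. Of 2730 X-linked protein-coding genes 355 were listed, against 1761 of 17241 autosomal ones (odds ratio 1.31, two-sided Fisher's exact test, p = 1.80e-05). Over genes of all classes the odds ratio was 1.42 (Fisher's exact test, p = 3.37e-10), but it turned to 0.886 (Fisher's exact test, p = 0.0235) without piRNA genes. X-linked genes are longer, with a median span of 2508 bp against 1946 bp, and within span bins 350.2 were expected and no difference was found (odds ratio 1.02, exact test, p = 0.755). Among the autosomes the share ran from 6.07% on chromosome V to 14.4% on chromosome I.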

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

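Alternatives chosen before the data were examined were protein-coding genes as background, the 25th percentile of mean expression, random lists without matching, an adjusted p of 0.01 and 2-fold; the tests within span bins, against 2-fold, at 4-fold, by Bonferroni, with a mean of at least 100, without piRNA genes and on protein-coding genes for the correlations were chosen after the data were seen. No paired analysis was possible because the table holds no values per library. For that reason a replicate block, leaving out each replicate, count tests, other size factors, low value filters, pseudocounts and other set tests were not run, and what depth limits could not be measured. An adjusted p of 0.01 and 2-fold remove no gene, since the table already ends there, and say nothing about stability. The number of listed genes was 1779 by a two-sided Bonferroni p, 1350 by the test against 2-fold, 1465 at 4-fold or more and 1676 with a mean of at least 100, where 2732 are listed; each setting can only remove genes.

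With protein-coding genes as background, GLD-1 targets (odds ratio 2.81) and dynein (2.81) no longer passed, and the deficits of sperm (0.102) and neuronal genes (0.268) came to pass. Within span bins 6 lists were in excess, where 10 were against all reference genes: GLD-1 targets (1.41), P body (2.53), dynein (3.78) and muscle (2.49) lost the call. The deficits of ribosomal proteins (0.232) and collagens (0.338) lost it too, those of sperm (0.0712) and neurons (0.232) passed, and the X chromosome's odds ratio fell to 1.02. Histones in the shortest bin raised the number of sperm genes expected, and neither the sperm nor the neuronal deficit was tested without histones. Most of the neuronal list is neuropeptide genes, none of them listed, and its deficit was not tested without them. Counting only genes past the test against 2-fold, dynein (4.98), ribosomal proteins (0.221) and collagens (0.197) no longer passed, and structural non-coding RNAs turned to 1.04. That turn was absent without piRNA genes in the background (0.603), where dynein (3.304) and ribosomal proteins (0.147) also did not pass the same count. Without piRNA genes and with all listed genes counted, GLD-1 targets (3.62) no longer passed, sperm (0.126) and neuronal genes (0.346) came to pass, and the X chromosome turned to 0.886. With a mean of at least 100, ribosomal proteins (0.175) no longer passed and meiosis (5.50) did, but all 4 listed meiosis genes lie above that mean and only other genes were removed, so this setting says nothing about stability. Histones, germline RNA-binding proteins, FBF targets, cell cycle, vitellogenins and mitochondrially encoded genes kept their excess past the threshold with protein-coding genes as background, within span bins, past the test against 2-fold, and in both settings without piRNA genes. The lists of FBF targets and germline RNA-binding proteins share listed genes and are not independent.

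Fold against mean expression turned from -0.44 to 0.047 above the 25th percentile of the mean and to 0.10 in protein-coding genes other than histones with a mean of at least 100. Fold against span turned from -0.43 to 0.043 and 0.32 in the same sets and was -0.020 in protein-coding genes; of these 3 values 0.32 alone passed. In protein-coding genes fold against mean expression stayed negative (-0.086, permutation test, Benjamini-Hochberg adjusted p = 0.000126). For these and the other changes of call the cause was not tested.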

Other observations

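The tests in this part were all chosen after the values were seen. Genes for nucleoporins, the proteins of the nuclear pore, were listed far more often than their span predicts. Of 26 genes of the *npp* family 16 were listed, where 5.01 were expected (odds ratio 11.3, two-sided exact test within 20 span bins, Benjamini-Hochberg adjusted p = 2.29e-05 over 179 gene families of at least 10 members). In the authors' deposited table *npp-7* stood at 2.199 ± 0.099, *npp-21* at 1.93 ± 0.078, *npp-3* at 1.84 ± 0.11, *npp-12* at 1.66 ± 0.071 and *npp-6* at 1.24 ± 0.087 (log2 fold change ± SE). Without span bins 16 families in excess and 17 in deficit passed the Fisher's exact test, and within them 2 passed, both in excess, histones and nucleoporins. The background of this test holds genes that are not expressed in adults.

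Long genes were listed more often and, among the well measured ones, at higher folds. Greater power to detect long genes raises the chance of passing and not the fold, so alone it would not give the higher folds (Spearman's rho = 0.32). That rho is the observation itself and no separate test. For the share listed, power stays open. The rho over all listed protein-coding genes (rho = -0.020) cannot decide it, since that set holds no unlisted genes. It also holds the short histones with their high folds, and genes with low means that enter only with high folds. A candidate explanation is priming: cDNA of the inputs started at poly(A) tails, and that of the immunoprecipitates is taken not to have. This could leave the 5′ parts of long mRNAs thin in the inputs. In the well measured genes log2 fold rose by 0.25 per doubling of span (bootstrap 95% interval 0.20 to 0.30). Priming and immunoprecipitation cannot be told apart, however, because each group had its own library preparation. A preference of DLC-1 complexes for long RNAs stays open, as untested.

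The high folds of histone genes may come from the same difference. If oligo-dT primed inputs miss RNAs without poly(A) tails, histone genes whose mRNAs are known to carry tails, the H3.3 variants and the linker H1 genes, are listed less often, and 0 of these 14 (6 of the unlisted *his* genes and 8 *hil* genes from outside the histone list) were listed against 63 of the 66 other histone genes (two-sided Fisher's exact test, p = 4.51e-13). The unlisted *his* genes were known when this split was made, and the expression of the 14 genes is not known here. The test therefore cannot single out poly(A) tails as the cause. Reads shared among near-identical copies stay open: with each of 55 sets of near-identical values counted once the median log2 fold change was 7.87, but a set keeps the fold of its members, so this decides nothing. Binding of histone mRNAs by DLC-1 complexes was not tested and is not excluded.

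The excess of germline RNA-binding protein genes is not accounted for by their span (exact test within 20 span bins, unadjusted p = 3.18e-09). A background that holds unexpressed genes, which could raise any germline list, stays open. Without the genes they share with this list, the 6 other germline lists together, sperm left out, had 23 of 91 genes listed against 20 of 45 (odds ratio 2.87, two-sided exact test within 5 span bins, p = 0.0282), and the exact p was 0.197 after Bonferroni correction for the 7 lists from which this one was picked. Expression levels of unlisted members were not analysed here, so a difference in level between the lists stays open, and so does priming. An association of DLC-1 complexes with these mRNAs is a hypothesis that immunoprecipitates from untagged worms, with libraries primed alike, could test.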
